A study of Mus musculus with 36 samples.

How the data were processed

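Liver RNA of 36 mice was listed in the labels, and the deposited table held 35 of them. Aged low isoleucine female replicate 6 had no column in the table used here and was not analysed here. Libraries were stranded mRNA libraries, per the labels' protocols. Reads were processed against mm10 with edgeR and limma, per the submitters' processing notes, which give no versions. The aligner and the read counter are not given in the sources used here.

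The values are log2 CPM, as deposited by the authors, for 14680 genes named by symbol. The lowest value of the table is -3.75 log2 CPM (0.0745 CPM), which corresponds to a prior count of 2.00 reads scaled to the size of the library. Antilogs summed to between 860677 and 1128943 per library, so a scaling factor between libraries is part of the values. Between 87.5% and 91.2% of the low values of a library (below 100 reads) came out as whole reads within 0.02 reads, and the rest were fractional, as estimated counts would be. Recovered reads in the table ranged from 22.29 to 35.7 M (mega) per library, with group means between 25.97 and 27.76 M, and the 10 most abundant genes took 17.2% to 26.5% of them. At the mean effective library of 26.9 M reads, 1 read is worth less than the floor of the table, and between 39 and 200 genes per library lay at that floor. The 13 protein-coding genes of mitochondrial DNA are in the table under symbols without the mt prefix, so the list fixed for them matched no symbol and was not tested as planned; they were examined after the data had been seen. Positions of genes were taken from the GENCODE vM21 annotation of GRCm38, in which 14185 symbols (96.6%) have a single position.

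Since the values are logged and not counts, they were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 6 groups over all 35 libraries, which then share 1 estimate of the spread per gene, with moderated variances that follow a trend on mean expression. Adjusted p-values are Benjamini-Hochberg values over 14680 genes within a comparison, and 0.05 was the threshold. The comparisons were diet within each sex of aged mice, age within each sex of control mice, the 2 interactions with sex, sex within each of the 3 conditions, and aged low isoleucine against young control in each sex. All statements on changed genes refer to this fit unless another is named. Mice are the replicates. No pair of libraries of a group was identical or agreed within counting noise.

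A set of 39 gene lists (pathways, sex-biased liver genes and cell type markers) was fixed before the data were examined, and the 36 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes. The list of ribosomal protein genes was taken by symbol and includes pseudogene symbols. Camera was repeated with a correlation estimated for each list. After the data had been seen, an exact two-sided permutation test of the mean of each list per library was added for the 4 comparisons of diet and age within a sex, with Benjamini-Hochberg adjustment over 36 lists; the smallest p it can give is 0.00216. That permutation test exchanges mice as independent and does not allow for identifier numbers shared within a group. Expression of a list per library is the mean of its members relative to the mean of the 6 group means.

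Named genes follow a rule fixed before the data were examined. For each diet and age comparison within a sex it takes the 6 largest rises and the 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 log2 CPM and all but 1 or fewer libraries of each group on their side of the other group's median. The rule leaves out predicted genes, pseudogenes and genes of the sex chromosomes. It adds the 3 members with the smallest p of the 5 leading lists, 1 member of each other list past the threshold, and Fgf21, Asns, Fasn, Cyp7a1, Igf1 and Cdkn1a whatever their result. For the interactions it takes the 5 largest of each sign under the same limits on adjusted p, mean expression over the libraries compared and kind of gene, without the requirement on medians, and for sex Xist and 4 Y-linked genes and the 3 largest of each direction. The requirement on libraries, written for groups of 6, was applied as 4 of 5 in the group of 5.

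Alternatives fixed in advance were quantile normalization, centring on the median, a filter of 1 log2 CPM in at least 6 libraries, log2(CPM + 1), fits on the compared groups alone, robust moderation, array weights, the replicate number as a block, mice of a group sharing an identifier number as a random block, voom weights on recovered reads, and leaving out each library in turn. Sets of libraries left out together were added after the data had been seen. Correlations between diet and age effects, which share the aged controls, were set beside 100 simulated draws from the residuals of the same libraries.

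The procedure was also run on simulated data, independent values for the 14680 genes, in which 200 genes were changed. Each gene had its observed mean and, in every library, the same variance, averaged over those of the 6 groups. Of 100 genes changed by 1 log2 unit, 89 were recovered for the diet in males, 89 for the diet in females, 87 for age in males and 82 for age in females, and of 100 genes changed by 2, 98 were recovered in each. A list changed by 1 log2 unit was called in each comparison and no unchanged list was, and 9 to 14 unchanged genes passed. The simulation draws genes independently, so it holds none of the shared variation between genes that the libraries show. It also gives all groups an equal spread. Its recovery for the diet in females therefore does not cover the wider spread of those libraries (mean variance 0.290 in aged control and 0.498 in aged low isoleucine females). Figures were drawn with matplotlib 3.10.9.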

Results

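Messenger RNA was measured by RNA sequencing in livers of C57BL/6J.Nia mice, an inbred strain, of both sexes. Aged mice were 20 months old at the start and 24 months at the end of 4 months on a control diet or on a diet low in isoleucine, a branched-chain amino acid that mice cannot make. Young mice ate the control diet and were 6 months old at the start and 10 months at the end. All mice were killed after a 16 h overnight fast and 3 h of refeeding. The 35 libraries analysed here fell into 6 groups, with 6 mice in each of the young control, aged control and aged low isoleucine groups of males and in the young and aged control groups of females, and 5 mice in the aged low isoleucine group of females. The sixth mouse of that last group was not analysed here. The table held 14680 genes, and between 22.29 and 35.7 M estimated reads (M, mega) per library could be recovered from its values, with a median of 26.23 M. Values are log2 CPM, the reads of a gene scaled to the size of its library, fold changes are on that scale, and ± after a log2 change is a standard error (SE). Levels given in CPM are means of a group after the floor of the table, 0.0745 CPM, was subtracted.

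The sex labels held in every library. Xist, the RNA that silences 1 X chromosome in females, lay between 9.10 and 10.35 log2 CPM in the 17 female libraries and between -3.75, the lowest value in the table, and -1.75 in the 18 male libraries. The Y-linked genes went the other way: Ddx3y lay between 4.65 and 6.07 in males and at most at -2.70 in females, Uty between 2.54 and 3.76 against at most -2.70, Kdm5d between 4.07 and 4.83 against at most -3.21, and Eif2s3y between 5.53 and 6.20 against at most -2.70. The first principal component held 35.5% of the variance and the second 12.8%. Spread within groups was unequal. The mean variance within a group was 0.152 (young control males), 0.158 (aged control males), 0.170 (aged low isoleucine males), 0.241 (young control females), 0.290 (aged control females) and 0.498 (aged low isoleucine females) in squared log2 units.

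**Figure D1:**
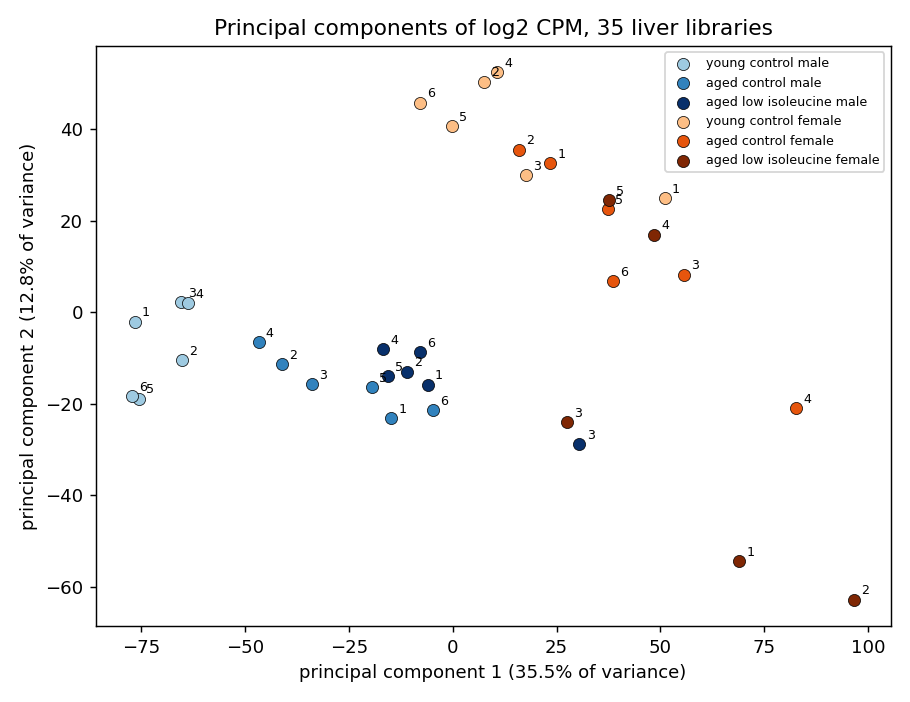
Each point is 1 library, numbered by replicate and coloured by group, on the first principal component (horizontal axis, 35.5% of variance) and the second (vertical axis, 12.8%), both in log2 units. Aged low isoleucine female replicates 1, 2 and 3 lie at lower values of the second component than replicates 4 and 5 of that group.

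The first comparison asks what the low isoleucine diet did to the liver of aged males. Genes that are normally high in male liver fell and genes that are normally high in female liver rose. Mup20, a major urinary protein (chromosome 4, 62050234 to 62054158 of GRCm38), went from 11.01 ± 0.93 (SD, n = 6) to 7.23 ± 1.0 log2 CPM (SD, n = 6), a change of -3.78 ± 0.42. Sult2a1, a sulfotransferase that is high in female mouse liver (chromosome 7, 13796246 to 13837409), rose from -2.87 ± 0.40 to 0.97 ± 1.68, a change of 3.84 ± 0.51. The SE of 0.51 rests on the spread shared by all groups and is smaller than these males' own spread for Sult2a1 implies. Genes of the amino acid response driven by the transcription factor ATF4 rose alongside, among them Trib3, a pseudokinase, and Fgf21, a hormone secreted by the liver, which rose by 2.58 ± 0.34 and 2.80 ± 0.56. Igfbp1, a binding protein for insulin-like growth factors (chromosome 11, 7197782 to 7202546), rose 23.5-fold, by 4.55 ± 0.71.

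In total 39 genes were higher and 38 lower in low isoleucine males at an adjusted p under 0.05, and 29 and 27 of these changed at least 2-fold. From the aged male libraries alone 124 were higher and 133 lower, mice sharing an identifier number as a random block gave 36 and 24, and leaving out 1 library at a time gave 33 to 62 and 23 to 50. Of the 19 measured male-biased liver genes, 8 fell, 0 rose and 11 did not pass (13 fell when adjusted over the list alone), with a median of -1.63. The falls included Hsd3b5, a steroid dehydrogenase (-3.66 ± 0.52, adjusted p = 8.88e-05), the cytochrome P450 Cyp4a12b (-2.85 ± 0.44, adjusted p = 0.000317) and Mup20 (adjusted p = 3.86e-06), each with 6 of 6 low isoleucine libraries below the control median, and the anion transporter Slco1a1 (-3.38 ± 0.63, adjusted p = 0.00403). Slc22a28, an anion transporter outside the list, fell as well (-2.60 ± 0.45, adjusted p = 0.00155). Of 22 female-biased liver genes, 6 rose and none fell (12 rose when adjusted over the list alone), with a median of 2.0. They included Sult2a1 (adjusted p = 2.71e-05), its relative Sult2a2 (3.66 ± 0.54) and the cytochromes Cyp2b13 (5.81 ± 1.13, adjusted p = 0.00652) and Cyp3a41a (3.47 ± 0.71, adjusted p = 0.00836). The transporter Slc22a26, outside the list, rose too (2.92 ± 0.41, adjusted p = 8.24e-05). Sult2a1 reached 3.16 CPM in low isoleucine males against 735 CPM in aged control females. Reads of the Mup, Cyp and Sult2a genes can be shared between near-identical paralogs, so values of single members are uncertain.

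Of the 32 amino acid response genes, 6 rose and none fell (17 rose when adjusted over the list alone), with a median of 0.56. Trib3 (adjusted p = 2.71e-05), Sesn2, a leucine-binding regulator of mTORC1 (1.40 ± 0.20, adjusted p = 8.88e-05), and Chac1, which degrades glutathione (2.99 ± 0.52, adjusted p = 0.00152), led the list, and Fgf21 had an adjusted p of 0.00718. Asns, asparagine synthetase, changed by 2.31 ± 0.85 and did not pass (adjusted p = 0.322). Trp53inp1, a p53-induced gene (chromosome 4, 11156431 to 11174379), rose by 1.78 ± 0.23 (adjusted p = 1.76e-05), while Cdkn1a, the cell cycle inhibitor p21, changed by 1.48 ± 0.44 (adjusted p = 0.137). Cidea, a lipid droplet protein, fell by 3.11 on the log2 scale (adjusted p = 0.0135), the 1 of 15 lipid droplet genes to pass, with a list median of -0.46 (adjusted p = 0.194 with an estimated correlation; 2 fell when adjusted over the list alone). Fasn (-0.13 ± 0.52), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.99 ± 0.37), and Igf1 (-0.13 ± 0.17) did not pass, with adjusted p of 0.974, 0.339 and 0.894.

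Of 36 gene lists tested with camera, 10 were higher and 5 lower in low isoleucine males. The male-biased, amino acid response and female-biased lists (adjusted p = 4.99e-24, 3.67e-22 and 5.82e-22) kept their calls with an estimated correlation, at adjusted p = 0.00106, 0.00228 and 0.00566. The other 12 calls were lost with an estimated correlation, at adjusted p between 0.194 and 0.874. Among these were the 92 ribosomal protein genes (median 0.21, adjusted p = 0.506 with an estimated correlation), of which none passed singly, Rps24 (0.28 ± 0.10) being nearest. Also among them were 23 cholesterol genes (median 0.54, adjusted p = 0.739 with an estimated correlation), of which again none passed, as in Sqle (1.17 ± 0.49) and Mvk (1.02 ± 0.47), and 24 branched-chain amino acid catabolism genes (median -0.17, adjusted p = 0.653 with an estimated correlation). An exact permutation test of each list's mean per library, two-sided, called 5 lists (adjusted p = 0.0156 each): the 3 above, the lipid droplet list, and a growth hormone and IGF1 axis list that camera did not call. The call of that last list rests on its mean (0.34), as its median was -0.037, with 7 members positive and 8 negative. Igfbp1 was the 1 of its 15 members that passed, so no shift of the axis as a whole was shown. Aged low isoleucine male replicate 3 had the highest macrophage and cell cycle list values and the lowest oxidative phosphorylation value of its group. With voom weights on the recovered reads, Sult2a1, Sult2a2, Cyp2b13 and Cyp3a41a kept their direction and no longer passed, and Cidea no longer passed without aged control male replicate 6 or without low isoleucine male replicate 1 or 5.

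**Figure D2:**
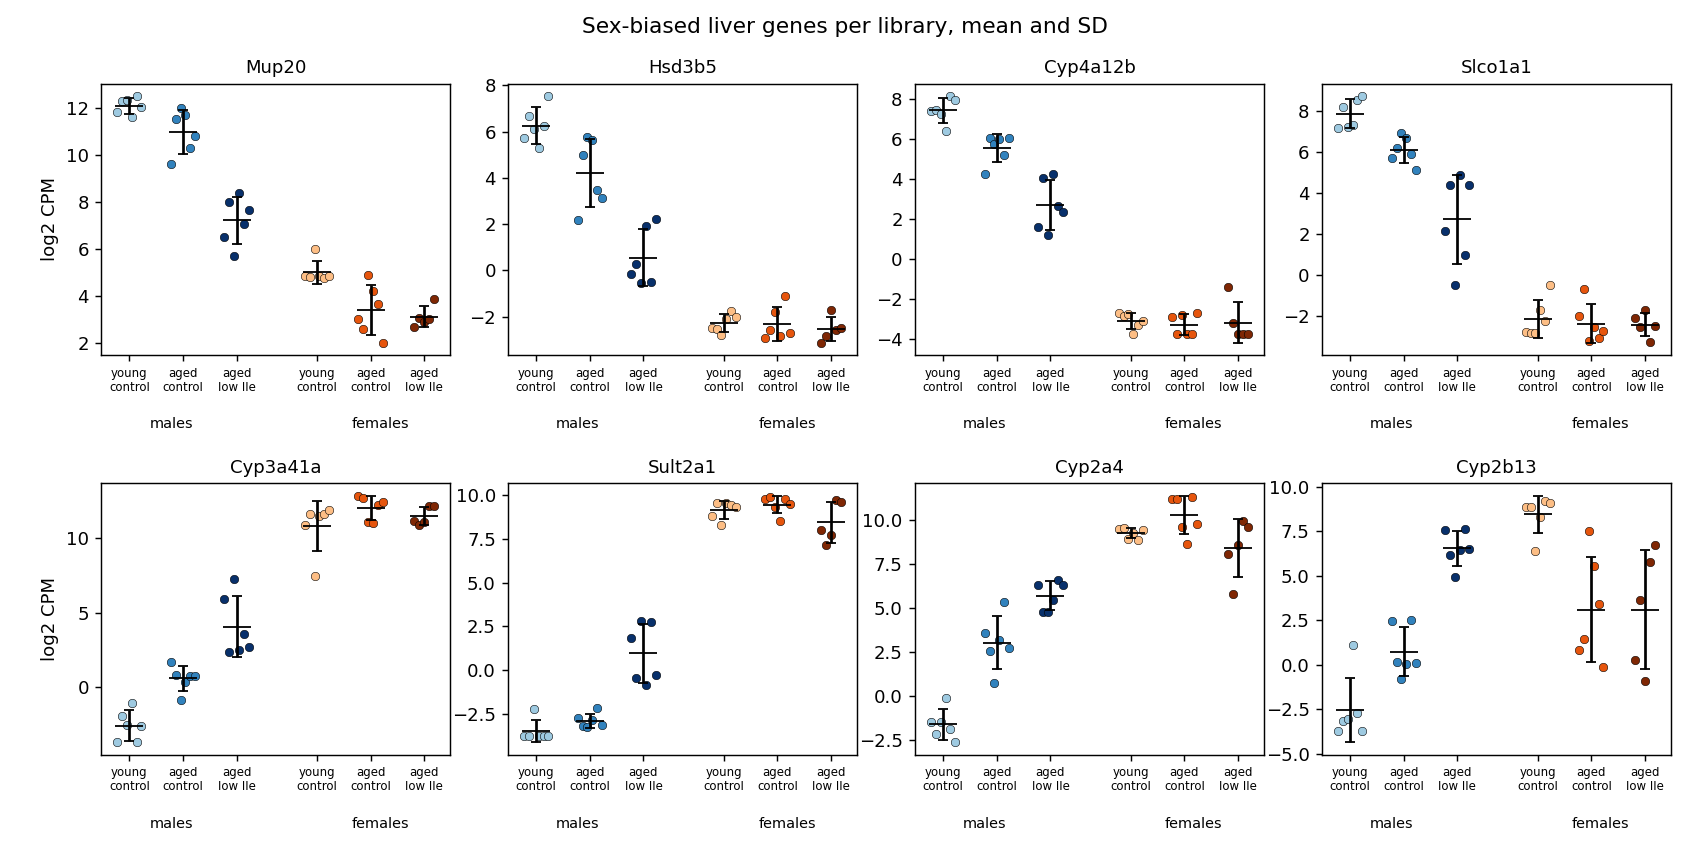
Each panel shows log2 CPM (vertical axis) of 1 sex-biased liver gene in every library, by group (horizontal axis), with bars for the mean and SD of the group. Mup20, Hsd3b5, Cyp4a12b and Slco1a1 are lower, and Sult2a1, Cyp2b13 and Cyp3a41a higher, in low isoleucine than in control aged males.

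In aged females the diet comparison gave a longer list of genes, which rested on few libraries. Trp53inp1 went from 4.83 ± 0.51 (SD, n = 6) to 7.26 ± 0.35 log2 CPM (SD, n = 5), a rise of 2.43 ± 0.24, with the highest control library below the lowest low isoleucine library. Igfbp1 (3.51 ± 0.75), Asns (3.54 ± 0.89), Chac1 (2.99 ± 0.54), Trib3 (2.05 ± 0.36) and Fgf21 (2.25 ± 0.58) were also higher, as was Ddit4, an inhibitor of mTORC1 induced by stress (2.89 ± 0.43, chromosome 10, 59949669 to 59951834). Of 77 nuclear oxidative phosphorylation genes 14 were lower and of 26 interferon response genes 6, with both list calls lost (adjusted p = 0.717 with an estimated correlation for each). Without replicates 1, 2 and 3 of the low isoleucine females the median of the interferon list was 0.21.

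In total 728 genes were higher and 663 lower in low isoleucine females, of which 258 changed at least 2-fold. From the aged female libraries alone 1 gene passed, Trp53inp1, although 2317 of 14680 genes had an unadjusted p under 0.05. Without replicates 1 and 2 of the low isoleucine females 28 genes passed, and without replicates 1, 2 and 3 it was 47. Of the 1391 genes, 1390 and 1339 kept the sign of their change in these fits, which share the controls and the remaining libraries with the full fit. These replicates stood apart. The erythrocyte list lay at 3.81 and 5.03 log2 above the mean of the 6 groups in replicates 1 and 2, against 0.10, -0.38 and -0.50 in replicates 3, 4 and 5, and the cell cycle list at 2.26 and 3.67 against -0.66, 0.45 and -0.08. The acute phase list lay at 1.44, 2.19 and 2.24 in replicates 1, 2 and 3 against 0.32 and 0.13, and the interferon response list at -1.86, -0.67 and -1.97 against 0.39 and -0.02.

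Of the 32 amino acid response genes, 10 rose and none fell in females (16 rose and 2 fell when adjusted over the list alone), including Ddit4 (adjusted p = 0.000529), Trib3 (adjusted p = 0.00178), Chac1 (adjusted p = 0.0021) and Asns (adjusted p = 0.0151). The call of the list was lost (adjusted p = 0.717 with an estimated correlation). Fgf21 had an adjusted p of 0.017 and Igfbp1 of 0.00656. Of 16 p53 target genes 4 rose (4 when adjusted over the list alone; adjusted p = 0.717 with an estimated correlation), with Trp53inp1 (adjusted p = 1.4e-07) and Cdkn1a (2.06 ± 0.46, adjusted p = 0.00865) among them. The largest rises also held Zbtb16, a transcription factor (2.58 ± 0.47). Of 77 nuclear oxidative phosphorylation genes 14 fell (44 fell and 1 rose when adjusted over the list alone), with a median of -0.35 (adjusted p = 0.717 with an estimated correlation), as in Ndufc1 (-0.61 ± 0.17), Atp5g1 (-0.54 ± 0.16) and Ndufs8 (-0.53 ± 0.16). Of 26 interferon response genes 6 fell (20 when adjusted over the list alone), with a median of -0.83 (adjusted p = 0.717 with an estimated correlation), including Bst2 (-1.07 ± 0.23), Oas1a (-1.27 ± 0.33) and Oasl1 (-1.05 ± 0.28). Of 14 heat shock genes 5 fell (7 when adjusted over the list alone; adjusted p = 0.717 with an estimated correlation), including Hspe1 (-0.58 ± 0.15), Dnaja1 (-0.84 ± 0.22) and Dnajb1 (-0.85 ± 0.25), and of 92 ribosomal protein genes 5 rose (5 when adjusted over the list alone; adjusted p = 0.717 with an estimated correlation), including Rpl9 (0.39 ± 0.10), Rpl5 (0.39 ± 0.10) and Rps4x (0.35 ± 0.09).

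The largest falls in females were Mup17 (-5.66 ± 1.40), Mup15 (-5.60 ± 1.76), Mup19 (-4.49 ± 1.25), Mup16 (-4.20 ± 1.17) and Mup10 (-3.02 ± 0.82), neighbouring near-identical genes whose reads can be shared, and Car3, a carbonic anhydrase (-2.97 ± 0.90). The aged control females themselves spread widely for these genes, with 5.42 ± 4.63 log2 CPM for Mup17 (SD, n = 6). The SE of 1.40 for Mup17 rests on the spread shared by all groups and is smaller than these females' own spread implies. Single genes of other lists also passed: Kmo of tryptophan breakdown (-0.50 ± 0.11), Hibch of valine breakdown (-0.48 ± 0.15), Fads2, a fatty acid desaturase (-1.10 ± 0.33), Cpt2 of fatty acid oxidation (-0.53 ± 0.16), the cyclin Ccnd1 (-1.65 ± 0.47), the acute phase gene Saa3 (1.64 ± 0.49) and the immediate early gene Dusp1 (2.03 ± 0.43). Without low isoleucine female replicates 1, 2 and 3, Car3 (0.85), Ccnd1 (0.0113) and Cpt2 (0.0114) turned direction. Hbb-bs, a haemoglobin chain (1.57 ± 0.53), Fasn (-1.10 ± 0.54), Igf1 (0.24 ± 0.17) and Cyp7a1 (-0.23 ± 0.39) did not pass. Camera called 7 lists higher and 10 lower. Every one of the 17 calls was lost with an estimated correlation, at adjusted p between 0.717 and 0.722. The exact permutation test of list means per library called none of 36 lists, with 4 at an unadjusted p under 0.05, among them the p53 list (p = 0.00216, adjusted p = 0.0779) and the amino acid response list (p = 0.0108, adjusted p = 0.13). Of the 35 named genes that passed in females, Trp53inp1 was the 1 that passed under every alternative. With each library centred on its median, 435 genes were higher and 926 lower, and with mice sharing an identifier number as a random block it was 415 and 393.

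**Figure D3:**
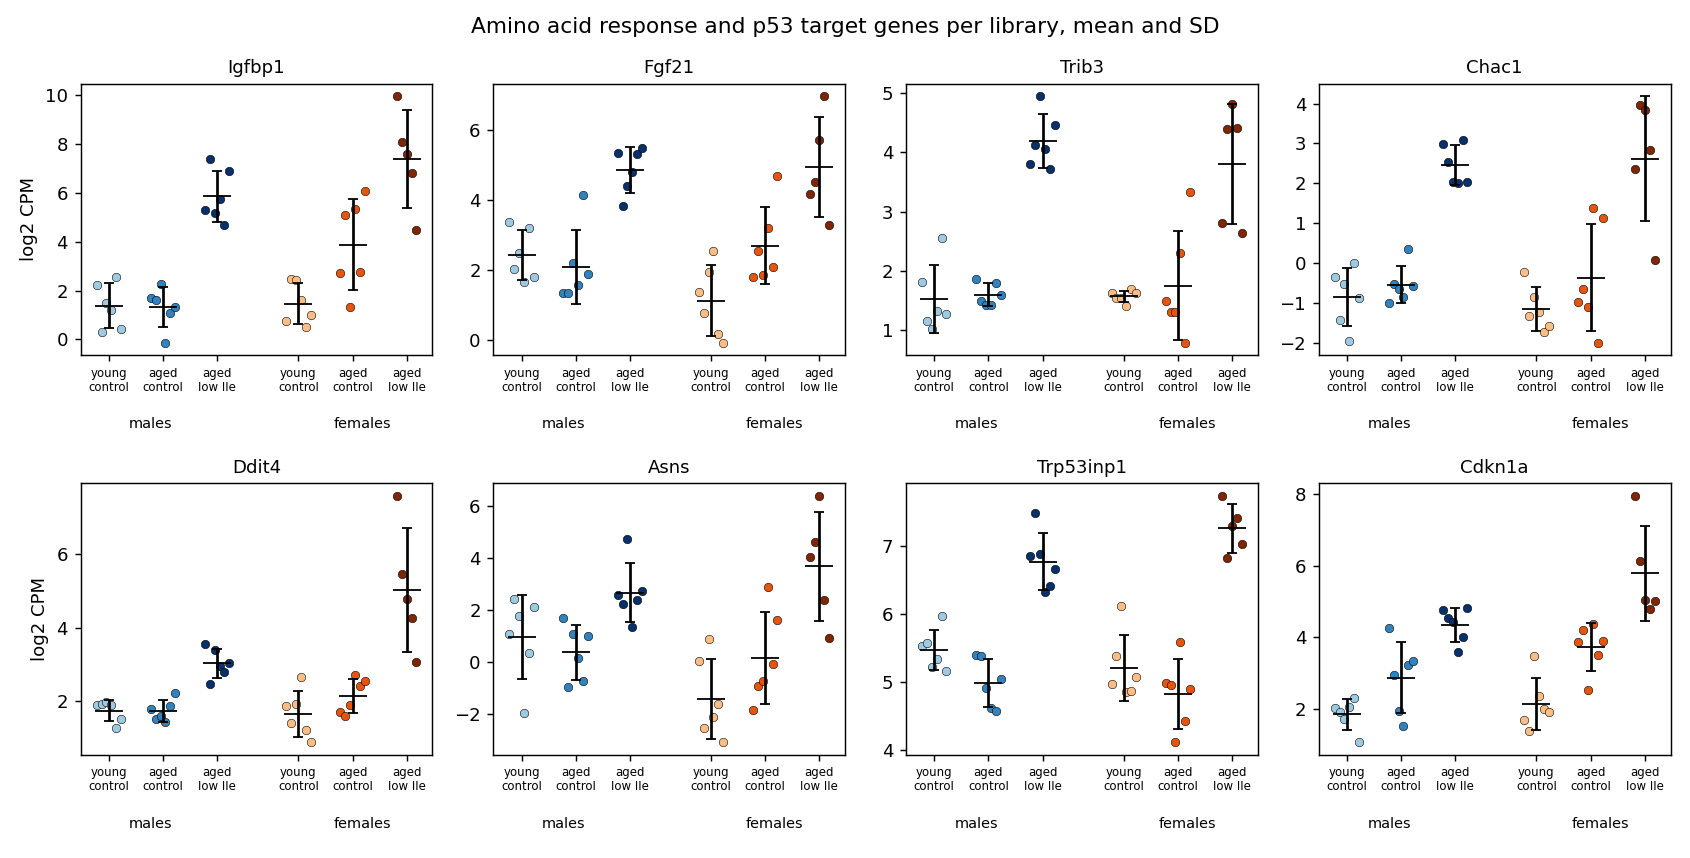
Each panel shows log2 CPM (vertical axis) of 1 amino acid response or p53 target gene in every library, by group (horizontal axis), with bars for the mean and SD. Trp53inp1 rises with the diet by 1.78 in males and 2.43 in females on the log2 scale.

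Whether the diet effect differed between the sexes was tested by the interaction, here the diet effect in females minus that in males. Sult2a1 (-4.87 ± 0.73), Sult2a2 (-4.21 ± 0.79) and the cytochrome Cyp2a4 (-4.55 ± 0.87) had more negative diet effects in females, as did the aldehyde dehydrogenase Aldh3b3 (-3.77 ± 0.66) and Osgin1, an oxidative stress gene (-2.47 ± 0.45). Mup20 (3.5 ± 0.61), the vesicular glutamate transporter Slc17a8 (3.04 ± 0.68), the cytochrome Cyp2d9 (2.57 ± 0.57), the complement gene C6 (2.03 ± 0.46) and the NADPH oxidase Nox4 (1.96 ± 0.45) had more positive ones. For Trib3, Fgf21, Igfbp1, Chac1 and Trp53inp1 the interaction did not pass, with adjusted p of 0.634, 0.781, 0.658, 1 and 0.349.

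The interaction called 22 genes with a positive and 18 with a negative value, 8 and 15 after centring each library, and 3 and 5 with mice sharing an identifier number as a random block. Array weights raised the counts instead, and leaving out 1 library at a time gave 6 to 101 and 7 to 74. From the compared groups alone, no gene passed (limma, 2010 genes at an unadjusted p under 0.05), and none of the 10 genes named for the interaction passed under every alternative. Camera gave 5 lists higher and 11 lower, led by the female-biased (median -2.41) and oxidative phosphorylation lists (median -0.29), all lost with an estimated correlation at adjusted p between 0.166 and 0.856. Across the 14680 genes, which are not independent replicates, diet effects in males and females correlated with Pearson's r = 0.212 and Spearman's rho = 0.166. Of the 77 genes called in males, 47 had the same sign in females, and of the 1391 called in females, 976 had the same sign in males. The calls shared 10 genes higher in both sexes, where 1.93 would be shared by independent lists, and 6 lower in both, where 1.72 would be.

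The next comparison is of aged with young males on the control diet. Genes of immune cells were among those higher in aged males. Lyz2, lysozyme of macrophages, went from 5.20 ± 0.17 (SD, n = 6) to 7.09 ± 0.49 log2 CPM (SD, n = 6), a rise of 1.89 ± 0.34, and Gpnmb, a macrophage glycoprotein, rose by 3.33 ± 0.73. The immunoglobulin genes Igha, Igkc and Ighm rose by 3.00 ± 0.87, 2.74 ± 0.69 and 2.58 ± 0.66. Elovl3, a fatty acid elongase (-2.19 ± 0.56), and Hsd3b5 (-2.06 ± 0.52) were lower, while Cyp2a4, a female-biased cytochrome, rose from -1.61 ± 0.86 to 3.02 ± 1.49, by 4.63 ± 0.60.

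In aged males 617 genes were higher and 174 lower, 414 and 27 of them at least 2-fold. Of 20 macrophage and Kupffer cell genes 16 rose (19 when adjusted over the list alone; median 1.39; adjusted p = 0.201 with an estimated correlation), including Lyz2 (adjusted p = 0.00164) and Cd5l (1.52 ± 0.33, adjusted p = 0.00926). Of 15 B and plasma cell genes 7 rose (14 when adjusted over the list alone; median 2.39; adjusted p = 0.201 with an estimated correlation), including Cd79b (2.58 ± 0.68). Of 18 T and NK cell genes 7 rose (11 when adjusted over the list alone; median 1.43; adjusted p = 0.281 with an estimated correlation), including Gzmb (1.95 ± 0.43), Cd8a (2.27 ± 0.55) and Ccl5 (1.99 ± 0.52). Neutrophil genes had a median of 2.01 with 1 of 10 past the threshold, Csf3r (1.48 ± 0.33), 7 when adjusted over the list alone, and adjusted p = 0.342 with an estimated correlation. Other rises were the acute phase genes Saa3 (2.32 ± 0.47) and Lcn2 (2.79 ± 0.78), the interferon gene Oas1a (1.41 ± 0.32), H2-DMb1 of antigen presentation (1.20 ± 0.36), Tff3, a trefoil factor (3.75 ± 0.94), and the cytochrome Cyp2b9 (4.11 ± 1.11). Cdkn1a changed by 1.03 ± 0.44 (adjusted p = 0.167).

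Of 25 fatty acid oxidation genes 4 fell in aged males (8 when adjusted over the list alone; median -0.35; adjusted p = 0.281 with an estimated correlation), including Cpt2 (-0.68 ± 0.15), Creb3l3 (-0.52 ± 0.12) and Slc25a20 (-0.47 ± 0.14). Of 24 branched-chain amino acid catabolism genes 3 fell (6 fell and 1 rose when adjusted over the list alone, adjusted p = 0.268 with an estimated correlation). They included Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase (-0.79 ± 0.21). Of 19 male-biased genes 6 fell (11 when adjusted over the list alone, adjusted p = 0.201 with an estimated correlation and 0.0504 by permutation). Cyp4a12b (-1.89 ± 0.44), Mup18 (-4.20 ± 1.07), Mup21 (-1.98 ± 0.49), the carboxylesterase Ces2c (-2.20 ± 0.37), the sterol transporter Abcg5 (-0.83 ± 0.21), Pfkfb1 of glucose metabolism (-0.58 ± 0.14), Kmo (-0.41 ± 0.11) and Cyp1a2 (-1.11 ± 0.33) were lower. The 77 oxidative phosphorylation genes had a median of -0.24 (adjusted p = 0.434 with an estimated correlation) with none past the threshold, Ndufv1 (-0.32 ± 0.10) being nearest. All 77 changes were negative, and the exact permutation test of the list's mean per library called the list lower (adjusted p = 0.0468). Fgf21 (-0.35 ± 0.56), Asns (-0.59 ± 0.85), Fasn (-1.04 ± 0.52), Igf1 (-0.15 ± 0.17) and Cyp7a1 (0.37 ± 0.37) did not pass.

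Camera called 9 lists higher and 13 lower in aged males, and with an estimated correlation all 22 calls were lost, at adjusted p between 0.201 and 0.717. The exact permutation test of list means per library called 16 lists, 14 of them among the 22, including macrophages (adjusted p = 0.013), B and plasma cells (adjusted p = 0.013), T and NK cells (adjusted p = 0.013), fatty acid oxidation (adjusted p = 0.0173), branched-chain amino acid catabolism (adjusted p = 0.013) and the female-biased list (adjusted p = 0.0173). The permutation test takes mice as independent and does not allow for shared identifier numbers. Of 33 named genes that passed, 5 did so under every alternative: Lyz2, Cd5l, Oas1a, Ces2c and Cyp4a12b. Counts fell to 173 higher and 74 lower with quantile normalization, to 104 and 71 with voom weights on the recovered reads and to 224 and 45 with mice sharing an identifier number as a random block, and rose to 1503 and 904 from the compared groups alone, and centring each library gave 523 higher and 261 lower.

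**Figure D4:**
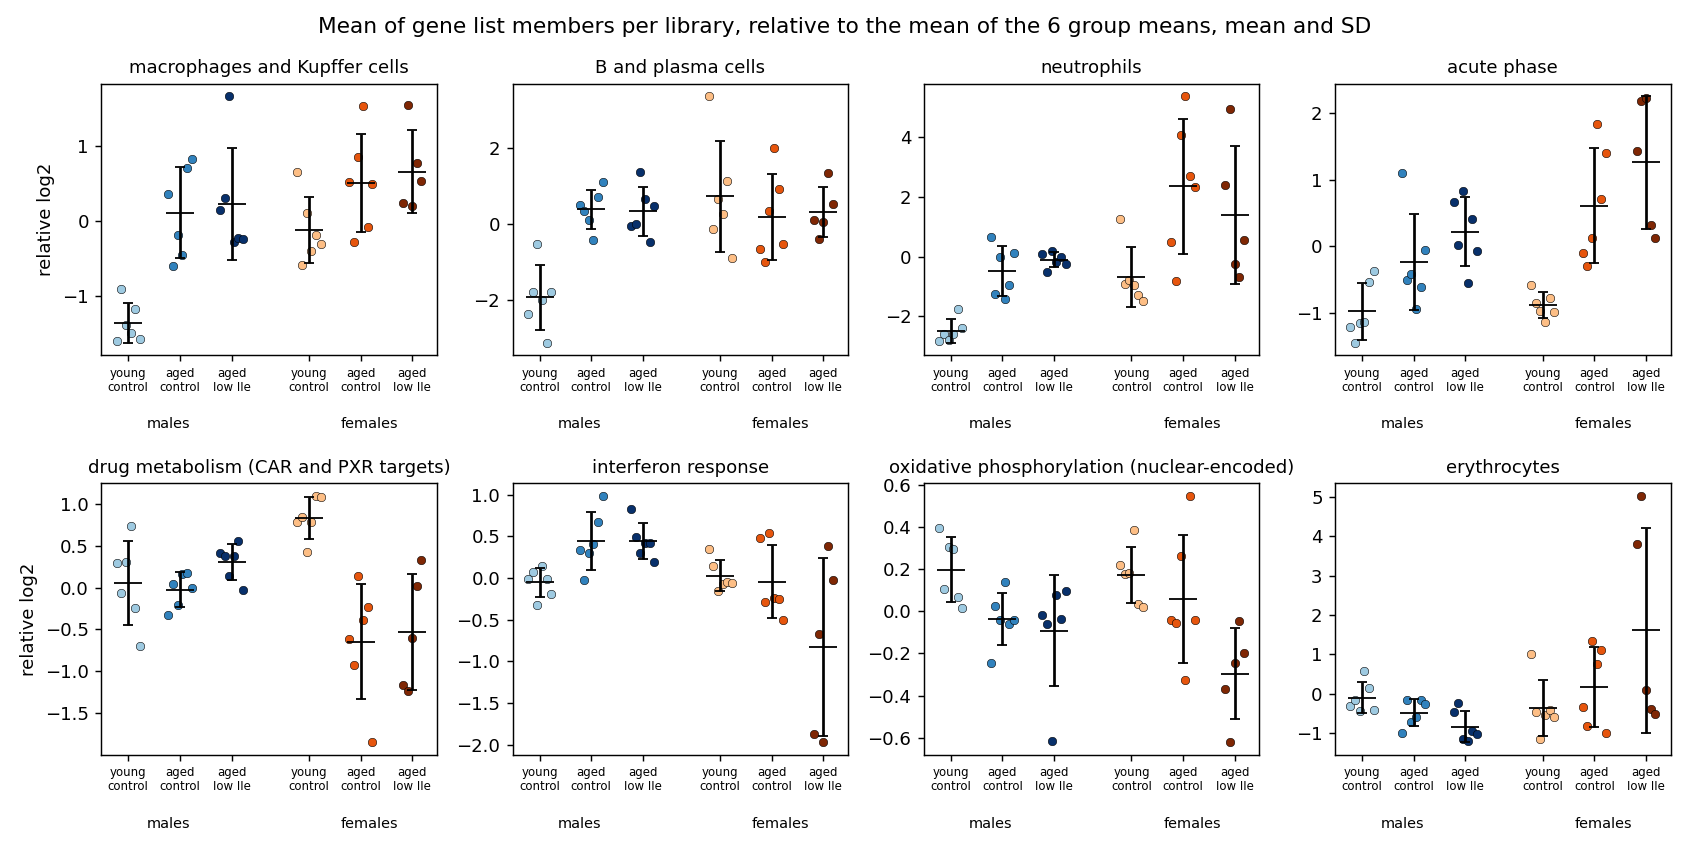
Each panel shows the mean of the members of 1 gene list in every library, relative to the mean of the 6 group means (vertical axis, log2), by group (horizontal axis), with bars for the mean and SD. Immune cell lists are higher in aged than in young control males, and the erythrocyte list reaches 3.81 and 5.03 in 2 aged low isoleucine females.

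In aged control females, single genes of the acute phase and of neutrophils were among the rises and genes of drug metabolism among the falls, while the calls of the lists were lost (adjusted p = 0.206, 0.275 and 0.114 with an estimated correlation). Lcn2, an acute phase protein that binds siderophores (chromosome 2, 32384633 to 32388252), went from 5.18 ± 0.55 (SD, n = 6) to 9.03 ± 1.60 log2 CPM (SD, n = 6), a rise of 3.85 ± 0.78. Chil3, a chitinase-like protein of myeloid cells, rose by 4.89 ± 0.73, and the neutrophil gene S100a8 by 3.75 ± 0.89. Cyp3a11, a main drug-metabolising cytochrome (chromosome 5, 145854426 to 145879964), fell from 11.13 ± 0.19 to 6.90 ± 2.60, a change of -4.23 ± 0.67. The SE of 0.67, and the adjusted p that follows from it, rest on the spread shared by all groups. That SE is smaller than these females' own spread implies. Hamp, hepcidin, the hormone that limits iron uptake, fell with a change of -3.03 ± 0.69, and Srebf1, a regulator of fatty acid synthesis, with -2.22 ± 0.39.

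In aged females 622 genes were higher and 408 lower, 291 and 137 of them at least 2-fold. Of 26 acute phase genes 17 rose and 1 fell (25 rose when adjusted over the list alone; median 1.29; adjusted p = 0.206 with an estimated correlation), including Lbp (1.07 ± 0.19), Cp, ceruloplasmin (1.33 ± 0.26), and Fgl1 (1.69 ± 0.33), each higher in 6 of 6 libraries than the young median. Of 10 neutrophil genes 9 rose (9 when adjusted over the list alone; median 3.55; adjusted p = 0.275 with an estimated correlation and 0.0877 by permutation), including Mmp8 (3.55 ± 0.79) and Csf3r (1.41 ± 0.33), and Ngp (4.32 ± 1.18) and Ltf (3.96 ± 1.19), both granule proteins, were among the largest rises. Of 22 drug metabolism genes 11 fell and none rose, with a median of -1.17 (adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, 15 fell and 1 rose. The falls included Cyp3a11 (adjusted p = 0.000228), the transporter Abcc3 (-2.39 ± 0.39, adjusted p = 0.000351), Cyp1a2 (-1.63 ± 0.33) and Cyp2b13 (-5.36 ± 1.13). Outside the list, Sult2a5 (-2.99 ± 0.61) and Gsta1, a glutathione transferase (-3.65 ± 0.54), fell too. Of 36 amino acid catabolism genes 6 fell (15 when adjusted over the list alone; adjusted p = 0.512 with an estimated correlation), including Tdo2 (-0.94 ± 0.21), Hpd (-0.64 ± 0.16) and Ass1 (-0.87 ± 0.25), as did 6 of 24 branched-chain amino acid genes (7 when adjusted over the list alone; adjusted p = 0.512 with an estimated correlation), including Hibadh (-0.84 ± 0.16), Acadsb (-0.70 ± 0.15) and Ppm1k (-0.79 ± 0.21).

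Further rises in aged females were the serpin Serpina1e (4.09 ± 0.94), Gldn (4.00 ± 0.73), Cyp4a31, a fatty acid hydroxylase (2.54 ± 0.28, adjusted p = 8.94e-07), Stat5a (0.81 ± 0.15), the triglyceride lipase Pnpla2 (0.70 ± 0.17) and Cdkn1a (1.59 ± 0.44, adjusted p = 0.0233). Further falls were Inmt (-3.29 ± 0.56), Etnppl (-3.12 ± 0.44), the lipoprotein receptor Vldlr (-2.21 ± 0.40) and the clock gene Nr1d2 (-0.70 ± 0.18). Of 18 clock genes 6 fell (8 fell and 2 rose when adjusted over the list alone, adjusted p = 0.206 with an estimated correlation). Macrophage genes had a median of 0.55 (adjusted p = 0.706 with an estimated correlation), with none of 20 past the threshold. Fgf21 (1.58 ± 0.56), Asns (1.56 ± 0.85), Fasn (-1.28 ± 0.52), Igf1 (-0.11 ± 0.17) and Cyp7a1 (-0.10 ± 0.37) did not pass. Camera called 8 lists higher and 8 lower, all 16 lost with an estimated correlation, at adjusted p between 0.114 and 0.845. The exact permutation test of list means called 6 of them: acute phase, drug metabolism, lipid droplet and glutathione lists (adjusted p = 0.0195 each) and the circadian clock and growth hormone lists (adjusted p = 0.039 each). Of 35 named genes that passed, 23 did so under every alternative. From the compared groups alone, 313 genes were higher and 204 lower, the random block of shared identifier numbers gave 398 and 246, and centring each library gave 445 higher and 508 lower.

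Few genes passed for the interaction of age with sex, taken as the age effect in females minus that in males. Cyp2b13 (-8.65 ± 1.60) and Cyp2b9 (-7.38 ± 1.56), female-biased cytochromes, and Vldlr (-2.79 ± 0.57) had more negative age effects in females, as did Sybu (-2.35 ± 0.42) and the transporter Abcc4 (-2.34 ± 0.53). Cyp4a31 (2.67 ± 0.39), the sulfotransferase Sult5a1 (2.72 ± 0.56), Nlrp12, a NOD-like receptor (2.49 ± 0.35), Ces2c (2.29 ± 0.53) and the transporter Slc16a13 (2.28 ± 0.48) had more positive ones. The interaction called 24 genes with a positive and 17 with a negative value, and Cyp4a31, Nlrp12 and Sybu passed under every alternative. With mice sharing an identifier number as a random block it called 6 and 3, and leaving out 1 library at a time gave 5 to 76 and 4 to 41. Camera gave 11 lists higher, led by fatty acid oxidation (median 0.61), and 9 lower, led by B and plasma cells (median -2.88), all lost with an estimated correlation at adjusted p between 0.290 and 0.733. Across genes the age effects of the sexes correlated with Pearson's r = 0.343 and Spearman's rho = 0.369. The calls shared 94 genes higher with age in both sexes, where independent lists would share 26.1, and 33 lower in both, where they would share 4.84.

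In young control mice 2227 genes were higher in females and 2101 in males, in aged control mice 792 and 890, and in aged low isoleucine mice 866 and 809. Quantile normalization gave 1330 and 1659, 696 and 898, and 713 and 959 in the same order. Cyp3a41a reached 2528 CPM in young females against 0.128 CPM in young males, a change of 13.45 ± 0.71, while in aged low isoleucine mice it was 3162 against 40.4 CPM, a change of 7.48 ± 0.74. Sult2a1 was at 596 CPM in young females, against 0.0238 CPM in young males, of which 5 of 6 libraries lay at the floor of the table, and Sult2a2 at 501 against 0.0503 CPM. Cyp3a41b and Cyp3a16 were also among the largest female excesses in aged mice, at 1075 against 0.0652 CPM for Cyp3a41b in aged controls and 182 against 0.361 CPM for Cyp3a16 in low isoleucine mice. On the male side, Mup7 was at 1355 CPM in young males, 323 in aged control males and 116 in low isoleucine males, against 0.117, 0.401 and 0.269 CPM in females. Cyp4a12a was at 344, 120 and 24.2 CPM in the same male groups. Cyp4a12b was at 185 CPM in young and 50.8 CPM in aged control males, and Mup3 at 1553 CPM in low isoleucine males against 98.1 CPM in females. Where a group lies near the floor, the log2 change depends on the prior count in the deposited values. In low isoleucine mice the counts were 125 and 142 when these 2 groups were fitted alone, and centring each library gave 640 and 1072.

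Aged low isoleucine mice were also set against young control mice, which differ in both age and diet. In males 1993 genes were higher and 1417 lower in the aged low isoleucine group, and in females 1994 and 1660. Centring each library turned the balance to 1659 higher and 2026 lower in males and to 1192 and 2533 in females, and in females quantile normalization gave 1705 and 2164. The remaining question was whether the diet moved genes towards their level in young mice. For each gene the diet effect was set against young minus aged control, so that a positive correlation would mean a move towards young. In males Pearson's r across genes was -0.229, with a covariance of -0.0395, where 100 simulated sets of unchanged groups sharing the aged controls gave a mean r of 0.490 (0.155 to 0.770) and a mean covariance of 0.0276 (0.00864 to 0.0555), so both observed values lay outside the simulated ranges. In females r was 0.0482 with a covariance of 0.0117, where the simulated means were 0.473 (-0.0918 to 0.881) and 0.0644 (-0.00669 to 0.241), so both lay inside the ranges. Observed minus simulated covariance was -0.0670 in males and -0.0527 in females. With the aged controls split into sets of 3, in 20 splits, mean r was -0.313 in males and -0.0973 in females. Of the genes called in males, 10 were lower with both diet and age, where independent lists would share 0.450, and 9 were higher with both, against 1.64. In the opposite direction 1 was higher with the diet and lower with age, against 0.462, and 1 lower with the diet and higher with age, against 1.60. Of those called in females, 56 were lower with the diet and higher with age, where independent lists would share 28.1, and 37 were higher with the diet and lower with age, against 20.2. In the same direction 14 were higher with both, against 30.8, and 15 lower with both, against 18.4. The aged controls enter both effects with opposite signs, which by itself raises overlaps of opposite direction above the values for independent lists.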

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

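The 3 patterns weighed first, and their tests, were chosen after the results were seen. For the shared spread, female RNA and single library explanations the deciding value had also been seen when the prediction was written; the other predictions were written before it was. Splits of libraries were drawn at random.

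More genes passed for the diet in aged females (1391) than in aged males (77). Replicates 1 and 2 of the low isoleucine females could carry this, with 28 genes passing without both, 332, 312 and 602 without 1 and either 3, 4 or 5, 321, 984 and 1350 without 2 and either of these, and 3529 without 4 and 5, while counts were mixed for replicate 3 (1908 and 2454 without it and 4 or 5). A spread shared with less variable groups fits too, with 1 gene passing from the aged female libraries alone against 257 from the aged male libraries alone, the reverse order. Blood cells in the libraries could account for a part, as 499 genes passed in females with the erythrocyte list value as a covariate. That was still more than the 132 in males. For the genes called in females, the median size of the change was 0.51 after and 0.58 before, on the log2 scale (SE 0.16 both times). A linear covariate of 1 list cannot set a limit on the part of blood cells. A stronger response of females to the diet was not separable from these, and 5 of 100 splits gave as many genes.

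Sex-biased liver genes shifted in low isoleucine males. Female RNA or a wrong label was excluded, as Xist stayed at 0.109 CPM where the share of Sult2a1 would have given 2.71 CPM. A single library was excluded, with a median of the male-biased list of -1.25 at its smallest size. Scaling (median -1.61 under quantile normalization) was excluded too. With male-biased members grouped by the stem of their symbol, all Cyp genes as 1 group, the median over groups was -1.63, and 0 of 13 groups were higher. The shift was thus not confined to 1 stem, but sharing of reads between paralogs was not itself tested. A response to the diet, which the groups differ in, was not excluded; its mechanism was not tested.

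Ribosomal protein genes had positive medians with the diet in both sexes, but none of 92 passed in males and 5 in females, and the list calls were lost (adjusted p = 0.506 and 0.717 with an estimated correlation). Without low isoleucine female replicates 1, 2 and 3 the female median was -0.0213. The median of the list lay at percentile 100 of lists matched on mean value and on length and GC content of the longest annotated transcript, in both sexes. Matched lists were drawn gene by gene, so this percentile does not allow for genes that move together by library. Matched lists themselves did not rise, with a median of -0.0326 in males and -0.239 in females. That argues against annotated length and GC content as the source of the positive medians. Lengths of the transcripts present in the libraries were not measured, so an effect of those was not tested. Whether the genes only move together by library could not be told (permutation p = 0.0390 in males and 0.255 in females). No biological explanation was tested.

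For numbers of genes called, fewer than 5 of 100 splits gave as large a count in 10 of 11 comparisons. If mice are taken as independent, chance in how libraries are grouped was unlikely in these, the 2 interactions aside. It was not excluded for age in females and for sex in low isoleucine mice, where another split called more genes than the real grouping. Splits for the interactions exchange libraries within each sex, which also removes any effect that both sexes share. They test for no effect in either sex and cannot decide whether chance explains a difference between the sexes. However, 23 libraries share an identifier number with another of their group (consensus correlation 0.176), and random splits break these sets apart. No splits were drawn under that number as a block. Chance therefore stays open in every comparison if mice sharing a number are not independent. With that number as a random block, diet by sex gave 3 positive and 5 negative genes and age by sex 6 and 3. The splits with a count as large, the real one included, were 1 of 100 for diet in males (77 genes, highest other 16), 4 for diet by sex (40, highest other 778), 1 for age in males (791, highest other 9), 2 for age in females (1030, highest other 1462) and 1 for age by sex (41, highest other 6). They were 1 for sex in young mice (4328, highest other 1885), 1 in aged controls (1682, highest other 125) and 2 in low isoleucine mice (1675, highest other 2260), and 1 each for low isoleucine against young in males (3410, highest other 351) and females (3654, highest other 3350). Chance could not be excluded for diet in females either (5 of 100, with 1391 genes and highest other 2749). For numbers of gene lists it could not be excluded in any comparison: 24 of 100 for diet in males (15 lists, highest other 24), 48 for diet in females (17, highest other 26), 58 for diet by sex (16, highest other 24), 5 for age in males (22, highest other 23), 28 for age in females (16, highest other 26) and 10 for age by sex (20, highest other 23).

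A library far from the others of its group was seen in 30 of 630 sets of values tested, where chance flags about 1 in 20 groups, or 31.5. The gap to the nearest library as a share of the range of the group is given for each. Aged control male replicate 5 stood out for Fgf21 (highest, 0.697), Chac1 (highest, 0.646) and Slc16a13 (highest, 0.73). Aged low isoleucine male replicate 2 stood out for Zfp36 (highest, 0.706). Aged control female replicate 1 stood out for Ccnd1 (highest, 0.708). Young control male replicate 5 stood out for Ces2c (highest, 0.731). Aged control male replicate 6 stood out for Cd79b (highest, 0.67). Young control male replicate 3 stood out for Cpt2 (lowest, 0.628) and Sult2a1 (highest, 1). For Sult2a1 the other libraries of that group tied at the floor of the table, which fixes the share at 1. The rate of 1 in 20 does not hold for such ties. Aged control male replicate 3 stood out for Cyp1a2 (lowest, 0.631). Aged control male replicate 4 stood out for Ebp (highest, 0.642) and Cyp3a41b (highest, 1), the latter again with the other libraries tied at the floor. Young control female replicate 1 stood out for Ltf (highest, 0.645), Csf3r (highest, 0.679), S100a8 (highest, 0.71), the neutrophils list (highest, 0.747), the liver sinusoidal endothelium list (lowest, 0.679), the cell cycle list (highest, 0.695) and the erythrocytes list (highest, 0.662). Young control female replicate 3 stood out for Cyp2b13 (lowest, 0.68), Cyp1a2 (lowest, 0.869), Cyp3a41a (lowest, 0.764) and the glutathione and NRF2 targets list (highest, 0.627). Aged low isoleucine female replicate 2 stood out for Osgin1 (lowest, 0.771). Young control male replicate 4 stood out for Cyp2b13 (highest, 0.783). Aged low isoleucine male replicate 3 stood out for Mup3 (lowest, 0.793), the macrophages and Kupffer cells list (highest, 0.696), the cell cycle list (highest, 0.633) and the oxidative phosphorylation (nuclear-encoded) list (lowest, 0.779). Aged control female replicate 3 stood out for the glucose metabolism list (lowest, 0.643).

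With all libraries fitted together, the interaction of diet with sex passed for the genes Aldh3b3 (-3.77), C6 (2.03), Cyp2a4 (-4.55), Cyp2d9 (2.57), Cyp4a12b (2.96), Hsd3b5 (3.44), Mup20 (3.5), Nox4 (1.96), Osgin1 (-2.47), Slc17a8 (3.04), Sult2a1 (-4.87) and Sult2a2 (-4.21), in log2 units, females minus males. None of the 10 genes named for this interaction passed under every alternative, and genes passing numbered 3 and 5 with the random block and none from the compared groups alone (limma, 2010 genes at an unadjusted p under 0.05). Camera at the preset correlation called the lists of female-biased liver genes (-2.41), oxidative phosphorylation (nuclear-encoded) (-0.29), interferon response (-0.77), male-biased liver genes (1.56), cholesterol biosynthesis and uptake (-0.74), T and NK cells (-0.91), erythrocytes (1.62), cholangiocytes (-0.85), heat shock (-0.48), MHC class II (-1.0), pericentral hepatocyte genes (-0.43), ER chaperones (-0.48), cell cycle (0.68), neutrophils (-1.56), glucose metabolism (0.21) and lipid droplet and PPAR gamma targets (0.37); the numbers are medians, and each list call was lost with an estimated correlation, at adjusted p between 0.166 and 0.856.

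The interaction of age with sex passed, again in the fit of all libraries, for the genes Abcc4 (-2.34), Ces2c (2.29), Creb3l3 (0.86), Cyp2b13 (-8.65), Cyp2b9 (-7.38), Cyp4a31 (2.67), Mup18 (7.0), Nlrp12 (2.49), Slc16a13 (2.28), Sult5a1 (2.72), Sybu (-2.35) and Vldlr (-2.79), in log2 units, females minus males. Of the 10 genes named for it 3 passed under every alternative, Cyp4a31, Nlrp12 and Sybu, and the random block left 6 and 3 genes. Camera at the preset correlation called the lists of fatty acid oxidation and PPAR alpha targets (0.61), B and plasma cells (-2.88), female-biased liver genes (-1.44), macrophages and Kupffer cells (-0.80), heat shock (0.56), acute phase (0.66), ER chaperones (0.58), drug metabolism (CAR and PXR targets) (-0.60), interferon response (-0.56), male-biased liver genes (0.86), T and NK cells (-0.96), MHC class II (-1.26), cholesterol biosynthesis and uptake (0.75), stellate cells and fibrosis (-0.55), lipid droplet and PPAR gamma targets (0.42), oxidative phosphorylation (nuclear-encoded) (0.0901), liver sinusoidal endothelium (-0.56), pericentral hepatocyte genes (0.23), bile acid synthesis and transport (0.22) and erythrocytes (0.93); the numbers are medians, and each list call was lost with an estimated correlation, at adjusted p between 0.290 and 0.733.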

How the results depend on the processing

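The 3 sets of libraries left out together, the permutation test of list means and the removal of single libraries from the correlations were chosen after the results were seen, and all other alternatives were fixed before. P-values measure the spread between these mice, as the labels describe them. In the main fit that spread is pooled over all 6 groups, which differ in spread. Named genes that passed also did so under every alternative in 13 of 18 for diet in males, 1 of 35 for diet in females, 5 of 33 for age in males, 23 of 35 for age in females, 0 of 10 for diet by sex and 3 of 10 for age by sex. The cause of each shift given below was not tested unless stated. Depth limits the genes near the floor of -3.75 log2 CPM, where the prior count sets the size of a fold change.

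Numbers of genes called moved by more than 1.5 times as follows, with the unlisted counts within that range. Quantile normalization gave age in males 173 higher and 74 lower, sex in young mice 1330 higher and low isoleucine against young males 1267 higher. Centring on the median gave diet in females 435 higher, diet by sex 8 higher and low isoleucine against young females 1192 higher and 2533 lower. With log2(CPM + 1) the counts were diet in males 58 lower, age in males 297 higher and age by sex 39 higher. Fitting the compared groups alone gave diet in males 124 higher and 133 lower, diet in females 1 higher and 0 lower, diet by sex 0 higher and 0 lower, age in males 1503 higher and 904 lower, age in females 313 higher and 204 lower, age by sex 85 higher and 45 lower, sex in low isoleucine mice 125 higher and 142 lower and low isoleucine against young females 615 higher and 556 lower; each fit then uses its own spread, and limma called no gene for diet by sex, with 2010 at an unadjusted p under 0.05. Array weights gave diet in males 258 higher and 322 lower, diet in females 321 higher and 337 lower, diet by sex 204 higher and 154 lower, age in males 1579 higher and 842 lower, age by sex 321 higher and 220 lower, sex in low isoleucine mice 1481 higher and low isoleucine against young males 2329 lower. Voom weights gave diet by sex 12 higher and age in males 104 higher and 71 lower. The filter on low values and robust moderation moved none of these counts beyond that range.

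With centring the share of higher calls moved by over 10 percentage points in 7 comparisons, to 435 higher and 926 lower (728 and 663 as deposited) for diet in females, 8 and 15 (22 and 18) for diet by sex, 523 and 261 (617 and 174) for age in males, 445 and 508 (622 and 408) for age in females, 640 and 1072 (866 and 809) for sex in low isoleucine mice, 1659 and 2026 (1993 and 1417) for low isoleucine against young males, and 1192 and 2533 (1994 and 1660) for the females; quantile normalization moved the last to 1705 and 2164.

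With the replicate number as a block, counts moved to diet by sex 4 higher and 9 lower and age by sex 43 higher, and other counts stayed within 1.5 times. The numbers do not pair the mice: correlations of same-numbered deviations ran from -0.141 to 0.232 for diet in males, -0.431 to -0.103 for diet in females, -0.115 to 0.146 for age in males and -0.387 to 0.291 for age in females, and a library correlated best with its own number in 2 of 6, 0 of 5, 1 of 6 and 1 of 6 cases. Mice of a group sharing an identifier number, taken as a random block, gave diet in males 24 lower, diet in females 415 higher and 393 lower, diet by sex 3 higher and 5 lower, age in males 224 higher and 45 lower, age in females 398 higher and 246 lower, age by sex 6 higher and 3 lower and sex in low isoleucine mice 515 higher.

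Without aged low isoleucine female replicates 1 and 2 the counts were diet in females 18 higher and 10 lower, diet by sex 4 higher and 4 lower, sex in low isoleucine mice 167 higher and 151 lower and low isoleucine against young females 569 higher and 417 lower. Without replicates 1, 2 and 3 they were diet in females 22 higher and 25 lower, diet by sex 11 higher and 6 lower, sex in low isoleucine mice 163 higher and 160 lower and low isoleucine against young females 207 higher and 203 lower. Without aged control female replicate 4, aged low isoleucine male replicate 3 and young control female replicate 1 they were diet in females 1297 higher and 1160 lower, diet by sex 282 higher and 193 lower, age by sex 75 higher and 49 lower and sex in low isoleucine mice 1452 higher. Fewer mice then enter the group.

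Numbers of gene lists called were diet in males 2 higher and 1 lower, diet in females 0 higher and 0 lower, age in males 0 higher and 0 lower, age in females 0 higher and 0 lower, diet by sex 0 higher and 0 lower and age by sex 0 higher and 0 lower with an estimated correlation, diet in females 6 lower, age in males 7 lower and age by sex 14 lower with quantile normalization, diet in males 3 higher and 2 lower, diet in females 0 higher and 0 lower, age in males 7 lower and age in females 3 higher and 3 lower with the permutation test, diet in females 4 higher without low isoleucine female replicates 1 and 2, and diet in females 3 higher and 2 lower without replicates 1, 2 and 3.

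The direction camera gives a list, set against all other genes, turned in these cases, with the median in brackets. Without low isoleucine female replicates 1 and 2 the diet effect in females turned for branched-chain amino acid catabolism (0.0458), amino acid catabolism and urea cycle (0.0762), cell cycle (-0.51), immediate early genes (-0.14) and erythrocytes (-0.26), and the diet by sex value for branched-chain amino acid catabolism (0.26), amino acid catabolism and urea cycle (0.18), bile acid synthesis and transport (0.24), cell cycle (-0.59) and immediate early genes (-0.58). Without replicates 1, 2 and 3 the diet effect in females turned for branched-chain amino acid catabolism (0.16), fatty acid oxidation and PPAR alpha targets (0.24), acute phase (-0.30), interferon response (0.21), T and NK cells (0.26), stellate cells and fibrosis (0.49), cell cycle (-0.18), immediate early genes (0.0408), ribosomal proteins (-0.0213) and erythrocytes (-0.44), and for the genes Car3 (0.85), Ccnd1 (0.0113) and Cpt2 (0.0114); the diet by sex value turned for branched-chain amino acid catabolism (0.32), fatty acid oxidation and PPAR alpha targets (0.45), drug metabolism (CAR and PXR targets) (0.66), acute phase (-0.82), interferon response (0.25), MHC class II (0.15), stellate cells and fibrosis (0.34), cell cycle (-0.29), heat shock (0.21), immediate early genes (-0.33) and erythrocytes (-0.41). Diet by sex also turned for the cell cycle list (0.0211) without aged low isoleucine female replicate 2, the lowest of a range up to 1.17, and for macrophages and Kupffer cells (0.58) without the farthest library of 3 other groups. The median itself kept its sign in these last 2 cases, for immediate early genes in females, replicates 1, 2 and 3 left out, and for diet by sex of branched-chain amino acid catabolism.

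Correlations across genes moved as follows. On filtered genes the diet effects of the sexes correlated at 0.274 (0.209 by Spearman, 0.166 over all genes) and the age effects at 0.385, and the diet effect against young minus aged in males at -0.308. With split aged controls it was -0.313 in males and turned to -0.0973 in females, where it also turned to -0.0140 without aged low isoleucine female replicate 4 and to -0.0449 without replicate 5.

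Leaving out each library in turn gave diet in females 122 to 1172 higher and 96 to 1124 lower, diet by sex 6 to 101 higher and 7 to 74 lower, age in females 303 to 681 higher and 180 to 463 lower, age by sex 5 to 76 higher and 4 to 41 lower, sex in aged controls 554 to 806 higher and 664 to 932 lower, diet in males 33 to 62 higher and 23 to 50 lower, age in males 236 to 625 higher and 64 to 152 lower, sex in low isoleucine mice 359 to 1242 higher and 370 to 1164 lower, low isoleucine against young females 1307 to 2369 higher and 1084 to 1987 lower, low isoleucine against young males 1490 to 1867 higher and 1078 to 1316 lower and sex in young mice 1602 to 2310 higher and 1588 to 2304 lower genes called. Lists called ran over diet in females 4 to 8 higher and 7 to 13 lower, diet by sex 2 to 6 higher and 10 to 13 lower, age in females 6 to 11 higher and 7 to 11 lower, age by sex 8 to 14 higher and 9 to 12 lower, diet in males 8 to 11 higher and 4 to 8 lower and age in males 8 to 10 higher and 11 to 14 lower. The correlations ranged over 0.128 to 0.242 for the diet effects of the sexes, 0.224 to 0.430 for their age effects, -0.273 to -0.100 for diet against age in males and -0.0449 to 0.164 in females.

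Single libraries whose removal moved a count of genes by more than 1.5 times were for diet in females, aged control female replicates 1, 3, 4 and 5 and aged low isoleucine female replicates 1, 2 and 5. For diet by sex they were aged control female replicates 1, 2, 3, 4, 5 and 6, aged control male replicates 1, 2, 3, 4, 5 and 6, aged low isoleucine female replicates 1, 2, 3, 4 and 5 and aged low isoleucine male replicates 1, 2 and 6. For age by sex they were aged control female replicates 2, 3, 4 and 6, aged control male replicates 3 and 4, young control female replicates 2 and 5 and young control male replicates 2, 3, 5 and 6. For age in females they were aged control female replicate 6 and young control female replicates 2 and 5. For age in males they were aged control male replicates 1, 3, 5 and 6 and young control male replicates 1, 3, 4, 5 and 6. For diet in males they were aged control male replicate 4 and aged low isoleucine male replicates 1 and 4. For sex in low isoleucine mice they were aged low isoleucine female replicates 1 and 2 and aged low isoleucine male replicates 1, 2, 4 and 5. For low isoleucine against young females they were aged low isoleucine female replicate 1.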

Other observations

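The 13 protein-coding genes of mitochondrial DNA, which encode subunits of the respiratory chain, were examined after the values had been seen. With age they were lower in both sexes as a set. In males ND2 fell by 0.67 and ND6 by 0.76 on the log2 scale (adjusted p = 0.0391 and 0.0487), and 11 of 13 did not pass (median -0.43). In females ND6 fell by 0.88 (adjusted p = 0.0185), and 12 of 13 did not pass (median -0.50). The exact permutation test of their mean per library gave an unadjusted p of 0.00216 in males and 0.0108 in females. With the diet none of 13 passed in either sex, with medians of 0.00 in males and -0.09 in females and permutation p of 0.978 and 0.552.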
